A study of Mus musculus with 6 samples.

How the data were processed

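The series holds 6 RNA-seq libraries of mouse retina at embryonic day 14.5, of which 3 are controls with floxed Ronin (Thap11) alleles and 3 are CKO retinae that also carry a transgene for Cre fused to GFP. Groups and replicate numbers were taken from the sample titles and genotype labels. Per the labels' protocols, total RNA was poly-A selected and fragmented cDNA was ligated to standard Illumina adaptors, and the series' design text names an Illumina HiSeq instrument. The kit and whether strand was kept are not given in the sources used here, so reads of a gene and an antisense partner cannot be told apart. The labels give a mixed strain background for the mice.

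The authors deposited 1 table of whole-number read counts per gene symbol for all 6 libraries. Per the submitters' processing notes, BWA 0.7.6a-r433, HTSeq 0.5.4p3, DESeq 2.13 and genome build mm9 were used, with no roles, annotation or settings recorded. The deposited counts are raw, with library totals of 25362936, 24903912 and 26280045 reads in control replicates 1 to 3 and 28504391, 25916532 and 23721052 reads in CKO replicates 1 to 3. The table lists 23441 distinct genes, 19085 with at least 1 read, and 0 rows that name no gene. It ends with 3 lines of a version-control merge conflict and 1 blank line, which were skipped, and 1 gene listed more than once with identical counts, which was kept once. The 20 most abundant genes took between 4.28% and 4.71% of a library's reads. Counting by gene symbol on mm9 can divide or discard reads of near-identical copies, such as alkaline phosphatase and zinc finger genes, and the annotation the authors used is not given in the sources used here. Coordinates are not printed, since the reference used here is of another build than the counts.

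Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr (minimum count 10), which left 14609 genes and removed 8832, libraries were scaled by TMM, and genotypes were compared with the quasi-likelihood F test (glmQLFit and glmQLFTest) in a model with genotype only, which was fixed before the data were examined together with the gene lists, the rule for named genes and all alternatives except where stated. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Log2 fold changes are CKO minus control, and their SE is the absolute log2 fold change divided by the square root of F. Printed levels are CPM, counts per 1000000 reads of the TMM-scaled library size, with the SD over 3 libraries; where a group had 0 reads, a limit of 3 counts over the group was used. Such limits cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of libraries agreed within sampling noise: the lowest chi-square per degree of freedom was 5.77.

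Gene lists were written from textbook knowledge: complex I subunits, complex I assembly factors, complex II and III genes, complex IV genes, complex V genes, mitochondrially encoded genes, mitochondrial ribosomal proteins, mitochondrial protein import, mitochondrial DNA maintenance and expression, pyruvate dehydrogenase and citric acid cycle, glycolysis, cytosolic ribosomal proteins, S-phase, G2 and M phase, G1 cyclins, kinases and inhibitors, p53 targets, integrated stress response targets, hypoxia-inducible factor targets, NRF2 targets, apoptosis machinery, retinal progenitor, neurogenic precursor, ganglion cell, photoreceptor precursor, amacrine and horizontal cell, ciliary margin and optic stalk, pigment epithelium, lens, blood vessel, periocular mesenchyme, microglia and macrophage, and erythroid markers, immediate early and heat shock genes, and THAP11 partners and MMACHC. These were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 33 lists that had at least 3 tested members. The list of mitochondrially encoded genes was not analysed here. Further lists were reported as values: Y-linked genes and Xist, and neighbours of Thap11. Each list also has the number of members past the gene test over all genes and adjusted over the list alone. Named genes were Thap11, Hcfc1, Zfp143 and Mmachc, the 6 largest rises and 6 largest falls among called genes with a mean log2 CPM of at least 1 and no overlap between groups, and from each list the 2 called members with the largest change (up to 4 in 6 of the lists), or the most abundant member where none was called; some genes that this rule names, and a list around such a gene, are not reported here.

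Alternatives were DESeq2 size factors, library sizes without a composition factor, DESeq2 1.42.0's Wald test, limma-voom, no filter beyond a total above 0, at least 1 CPM in 3 or more libraries, an adjusted p threshold of 0.01, the replicate number as a block, leaving out each library in turn, and for lists camera with an estimated correlation and fry. Removal of a per-library loess trend (span 0.3) over GC content and length was added after the data were seen, with GENCODE values for 99.2% of the tested genes. The gene test was tested on simulated data with 200 changed genes among 14480: it recovered 96 of 100 genes changed 4-fold and 35 of 100 changed 2-fold, and 12 of 143 calls (8.39%) were false. Camera on 200 simulated lists without change gave a p under 0.05 in 4. The simulated genes varied independently and the lists were drawn at random. That result therefore does not test camera where the genes of a list vary together. Neighbouring genes were found in the GENCODE annotation, and the shuffling test of called pairs was tested on simulated calls, where 3 of 100 random sets and 100 of 100 sets with 6 planted pairs passed.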

Results

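Polyadenylated RNA from mouse retinae at embryonic day 14.5 was sequenced in 3 control libraries and 3 libraries of a conditional knockout (CKO) of Ronin, the protein encoded by Thap11, a zinc finger transcription factor of the THAP family. Control mice carried floxed Thap11 alleles without a Cre transgene. CKO mice carried the same alleles together with a transgene that expresses Cre fused to GFP. The libraries held between 23721052 and 28504391 counted reads, and between 17108 and 17477 genes had at least 1 read in a library. The labels do not say whether the replicates of a genotype came from separate animals or litters, so the p-values measure the spread between these libraries, which may be in part technical. Pearson correlations of log2 CPM (counts per 1000000 counted reads) lay between 0.985 and 0.992 among the CKO libraries between 0.954 and 0.980 among the controls, where replicate 2 stood apart from the others, and between 0.954 and 0.988 across genotypes. Control replicate 3 correlated more highly with CKO replicates 2 (0.988) and 3 (0.983) than with either other control. The median SD of log2 CPM per gene was 0.326 among the controls, 0.194 among the controls without replicate 2, and 0.098 among the CKO libraries.

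The targeted gene was examined first in each library. Thap11 fell 7.78-fold in the CKO retina, to 12.9% of its control level. Its count was 1739, 1880 and 1880 in control replicates 1 to 3 and 323, 292 and 156 in CKO replicates 1 to 3. The mean was 74.0 ± 7.17 CPM in the controls and 9.49 ± 2.70 CPM in the CKO (SD, n = 3 per group), a log2 fold change of -2.96 ± 0.24 (SE, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.00425). Genes next to Thap11 were examined as values. None of the 7 measured neighbours (Ranbp10, Tsnaxip1, Cenpt, Nutf2, Edc4, Nrn1l and Pskh1) passed the test, and their median log2 fold change was 0.05. Edc4, the most abundant of them, stood at 136 ± 37.0 CPM in the controls and 140 ± 16.7 CPM in the CKO.

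The comparison of the genotypes asked which transcripts differ when Ronin is removed in the retina. Of 14609 genes tested with edgeR's quasi-likelihood test, 28 were higher and 103 lower in the CKO at an adjusted p under 0.05, so that 78.6% of the 131 calls were decreases. Changes of at least 2-fold made up 119 of the calls, 22 of them increases and 97 decreases. In all 131 called genes the CKO libraries did not overlap the controls. Among all tested genes 12.6% were separated in this way, where chance gives 10% for 3 libraries against 3. The steepest falls after Thap11 were those of Ctu1, a subunit of the enzyme that thiolates cytosolic tRNA, at a log2 fold change of -2.87 ± 0.24 (adjusted p = 0.00425), Macrod1, an ADP-ribose hydrolase, at -2.85 ± 0.44 (adjusted p = 0.0309), the small GTPase gene Rab7l1 at -2.81 ± 0.32 (adjusted p = 0.00994) and the histone methyltransferase gene Setmar at -2.71 ± 0.37 (adjusted p = 0.0200). Mmachc, which processes intracellular cobalamin (vitamin B12), fell 5.81-fold from 31.9 ± 12.1 to 5.48 ± 1.09 CPM (SD, n = 3 per group, edgeR adjusted p = 0.0165).

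Among the increases, Akp3, an intestinal alkaline phosphatase gene, had 0 reads in all 3 controls and between 146 and 173 reads in each CKO library. Against the limit of 3 counts over the control group, its CKO mean of 6.05 ± 1.01 CPM was at least 150-fold higher. Reads of Akp3 can be divided with closely related alkaline phosphatase genes, and Alppl2, singled out after its values were seen, likewise had 0 control reads and 88 to 101 reads per CKO library. The transcript 1700034P13Rik rose from 5, 2 and 3 reads in the controls to 233, 271 and 224 reads in the CKO, a log2 fold change of 6.04 ± 0.31 (edgeR adjusted p = 0.00122). BC030307 rose 10.4-fold, from 5.55 ± 1.70 to 57.5 ± 10.4 CPM (adjusted p = 0.00425). Park2, which encodes the E3 ubiquitin ligase parkin, rose 5.55-fold from 1.82 ± 0.35 to 10.1 ± 0.02 CPM (adjusted p = 0.00425). Abcd4, a lysosomal transporter in the cobalamin pathway, rose 5.76-fold from 19.9 ± 8.14 to 114 ± 7.79 CPM (adjusted p = 0.0101). The controls lacked the Cre transgene.

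The number of calls moved with the tool and with single libraries: DESeq2's Wald test called 117 genes higher and 196 lower, and edgeR called 6 higher and 10 lower without CKO replicate 3, 6 and 27 without control replicate 3, 8 and 33 without CKO replicate 1, 24 and 29 without CKO replicate 2, and 72 and 147 without control replicate 2. Of 16 named genes called besides Thap11, 11 (Mmachc, Abcd4, Macrod1, Rab7l1, Setmar, Eda2r, Uqcr10, Coa3, Mrpl24, Mrpl34 and Prim1) missed the threshold without CKO replicate 3, at adjusted p values of 0.0595 to 0.145, with 7 lost without control replicate 3, 7 without CKO replicate 1, 6 without CKO replicate 2 and 1, Eda2r, without control replicate 1. Macrod1 also missed it with limma-voom (adjusted p = 0.0522).

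**Figure D1:**
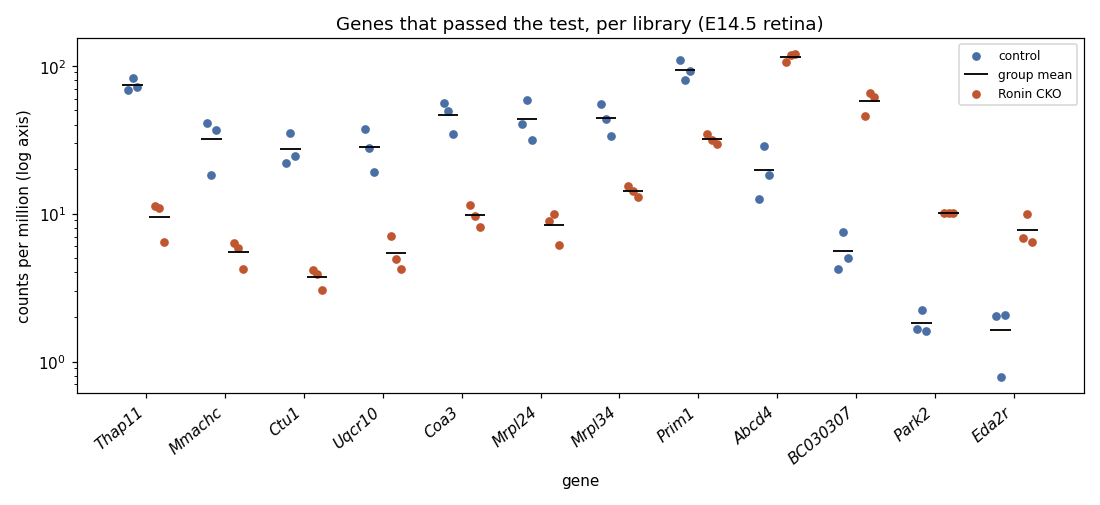
CPM on a log axis for 12 genes that passed the test; each point is a library (blue, control; orange, Ronin CKO; n = 3 per group) and each black line a group mean. The CKO points of every gene shown lie on 1 side of all control points, with Thap11 at a mean of 74.0 CPM in the controls and 9.49 CPM in the CKO.

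Mitochondrial genes were grouped by respiratory complex and by function. A few members of these groups fell steeply while the groups as a whole did not pass a set test. In the list of complex II and III genes, 1 of 22 tested members fell: Uqcr10, a small subunit of complex III, went from 28.1 ± 9.23 to 5.40 ± 1.48 CPM, a log2 fold change of -2.38 ± 0.30 (edgeR adjusted p = 0.0157). In the complex IV list, 1 of 29 fell: Coa3, an assembly factor of cytochrome c oxidase, went from 46.5 ± 10.9 to 9.77 ± 1.68 CPM (log2 fold change -2.25 ± 0.23, adjusted p = 0.00722). Of 79 mitochondrial ribosomal protein genes 2 fell, Mrpl24 by 5.19-fold (adjusted p = 0.0119) and Mrpl34 by 3.11-fold (adjusted p = 0.0146). None of the 35 complex I subunit genes passed the test, and their median log2 fold change was -0.04.

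None of the 15 complex I assembly factors (median 0.02), 20 complex V genes (median -0.11), 35 genes of mitochondrial protein import (median -0.03), 31 genes of mitochondrial DNA maintenance and expression (median 0.02) or 21 genes of pyruvate dehydrogenase and the citric acid cycle (median 0.02) passed the test over all genes. Their most abundant members were close in both genotypes: Acad9 at 64.5 ± 1.56 and 60.2 ± 1.13 CPM, Atp5b at 1017 ± 145 and 938 ± 46.4 CPM, Hspa9 at 287 ± 73.1 and 285 ± 10.4 CPM, and Mdh2 at 254 ± 49.3 and 251 ± 11.6 CPM in control and CKO. Gabpa, a transcription factor gene in the maintenance and expression list, was at 108 ± 35.0 and 130 ± 2.31 CPM. Adjusted over the list alone, Uqcr10, Coa3, Mrpl24, Mrpl34 and additionally Mtrf1, a mitochondrial release factor gene (log2 fold change -2.11 ± 0.43), were lower. The set test of these 9 lists (limma camera, Benjamini-Hochberg over 33 lists) gave adjusted p values of 0.932 for complex I subunits, 0.889 for assembly factors, 0.930 for complexes II and III, IV and V and for import, 0.839 for ribosomal proteins and for maintenance and expression, and 0.387 for the pyruvate dehydrogenase and citric acid cycle list. Control libraries decided some of these tests: without control replicate 1, complex I (adjusted p = 0.00474), complex IV (0.0276) and mitochondrial ribosomal proteins (0.00813) passed as higher, and without control replicate 3, complex I (0.0133), complex V (0.0337) and mitochondrial ribosomal proteins (0.00228) passed as lower, where the 11 alternatives to each test spanned up to 0.992.

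Genes of glycolysis and of the cytosolic ribosome were lower as sets by camera. Of 21 glycolysis genes 19 had negative log2 fold changes (median -0.24, camera adjusted p = 0.0422), and of 76 cytosolic ribosomal protein genes 62 did (median -0.27, adjusted p = 0.00168), while no member of either list passed the gene test, over all genes or adjusted over the list alone. With an estimated correlation both lists had an adjusted p = 0.982. Pkm, a pyruvate kinase gene, stood at 1062, 2564 and 1128 CPM in the controls and at 992, 1009 and 1156 CPM in the CKO, so that control replicate 2 lay apart. Rpl8 stood at 859, 1150 and 510 CPM in the controls and at 651, 581 and 646 CPM in the CKO. The glycolysis call was lost without control replicate 2 (adjusted p = 0.586), CKO replicate 1 (0.212) or CKO replicate 2 (0.149), within a range of 0.00423 to 0.982 over its alternatives, and the median difference on the log2 CPM scale went from -0.18 to -0.32 without control replicate 1 and to 0.00758 without control replicate 2. The ribosomal protein call was lost, with the direction of the test turned, without control replicate 1 (adjusted p = 0.436, range 3.8e-15 to 0.982), and its median difference went from -0.23 to -0.05 without that library and to -0.41 without control replicate 3.

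Cell cycle genes differed in few members. In the S-phase list, 1 of 36 genes fell, over all genes and adjusted over the list alone: Prim1, the catalytic subunit of DNA primase, went from 93.3 ± 14.6 to 31.9 ± 2.34 CPM, a 2.92-fold decrease (edgeR adjusted p = 0.00722). The median of the S-phase list was -0.07 (camera adjusted p = 0.839). None of 31 G2 and M phase genes passed (median -0.06, camera adjusted p = 0.387), and Top2a, a topoisomerase of proliferating cells, stood at 1203 ± 304 CPM in the controls and 983 ± 57.8 CPM in the CKO. Without control replicate 2 that list passed as lower (adjusted p = 0.00855, range 0.00855 to 0.982). None of 13 G1 cyclins, kinases and inhibitors passed over all genes or adjusted over the list alone (median 0.05, camera adjusted p = 0.839), with Ccnd1 at 4089 ± 191 and 3613 ± 275 CPM.

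Targets of p53 were higher as a set. Of 21 tested members 19 had positive log2 fold changes (median 0.20, camera adjusted p = 2.1e-05), against an adjusted p = 0.639 with an estimated correlation. Their median difference on the log2 CPM scale was 0.20, and 0.13 without control replicate 2 (adjusted p = 0.000333, range 8.3e-06 to 0.639). Eda2r, a receptor of the tumour necrosis factor receptor family, rose 4.71-fold from 1.63 ± 0.73 to 7.72 ± 1.92 CPM (edgeR adjusted p = 0.0459), and adjusted over the list alone Cdkn1a, a cyclin-dependent kinase inhibitor gene, was higher too, at 9.15 ± 0.31 and 13.7 ± 0.40 CPM. The Eda2r call, with adjusted p values up to 0.188 over its alternatives, was also lost with library sizes alone as the scaling (adjusted p = 0.0542). None of 22 integrated stress response targets passed over all genes (median 0.06, camera adjusted p = 0.162). Adjusted over the list alone, Chac1 and Asns were higher and Shmt2 was lower, and Slc7a5, the most abundant member, stood at 182 ± 20.5 and 236 ± 39.96 CPM. That set passed as higher without control replicate 2 (adjusted p = 0.00557) and without CKO replicate 3 (0.0466), in a range of 0.00557 to 0.982. No member passed, over all genes or adjusted over the list alone, among 16 hypoxia-inducible factor targets (median -0.06, camera adjusted p = 0.839, Slc2a1 at 802 ± 39.8 and 698 ± 58.2 CPM), 12 NRF2 targets (median 0.14, adjusted p = 0.138, Txnrd1 at 284 ± 73.0 and 331 ± 18.3 CPM), 20 apoptosis genes (median -0.03, adjusted p = 0.839, Mcl1 at 185 ± 8.99 and 173 ± 7.96 CPM) or 15 immediate early and heat shock genes (median -0.10, adjusted p = 0.930, Jun at 91.0 ± 15.2 and 83.2 ± 4.20 CPM).

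Markers of the retinal cell classes showed no call at this stage. No gene passed, over all genes or adjusted over the list alone, among 19 progenitor markers (median 0.02, camera adjusted p = 0.930), 15 neurogenic precursor markers (median -0.00229, adjusted p = 0.839), 19 ganglion cell markers (median -0.06, adjusted p = 0.930), 11 photoreceptor precursor markers (median 0.06, adjusted p = 0.839), 16 amacrine and horizontal cell markers (median 0.05, adjusted p = 0.612) or 10 ciliary margin and optic stalk markers (median -0.05, adjusted p = 0.839). Hes6 stood at 525 ± 341 and 329 ± 17.9 CPM, with 918 CPM in control replicate 2. The ganglion cell and neuronal tubulin gene Tubb3 was at 981 ± 98.7 and 1052 ± 30.2 CPM, and Neurod1, of photoreceptor precursors, at 144 ± 46.6 and 182 ± 19.1 CPM. Onecut2 was at 112 ± 17.1 and 84.0 ± 12.1 CPM, and Zic2 at 110 ± 25.97 and 128 ± 11.2 CPM. The amacrine and horizontal cell list passed as higher without control replicate 3 (adjusted p = 0.0337, range 0.0337 to 0.982). With 3 libraries per group at the observed depth, the simulated data recovered 96 of 100 genes changed 4-fold but 35 of 100 changed 2-fold. Differences of 2-fold or less in these markers could therefore go undetected. The simulation gave each gene the same spread in both genotypes, whereas the observed median SD was 0.326 among the controls and 0.098 among the CKO libraries. Its recovery is thus only a guide to that of these data.

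**Figure D2:**
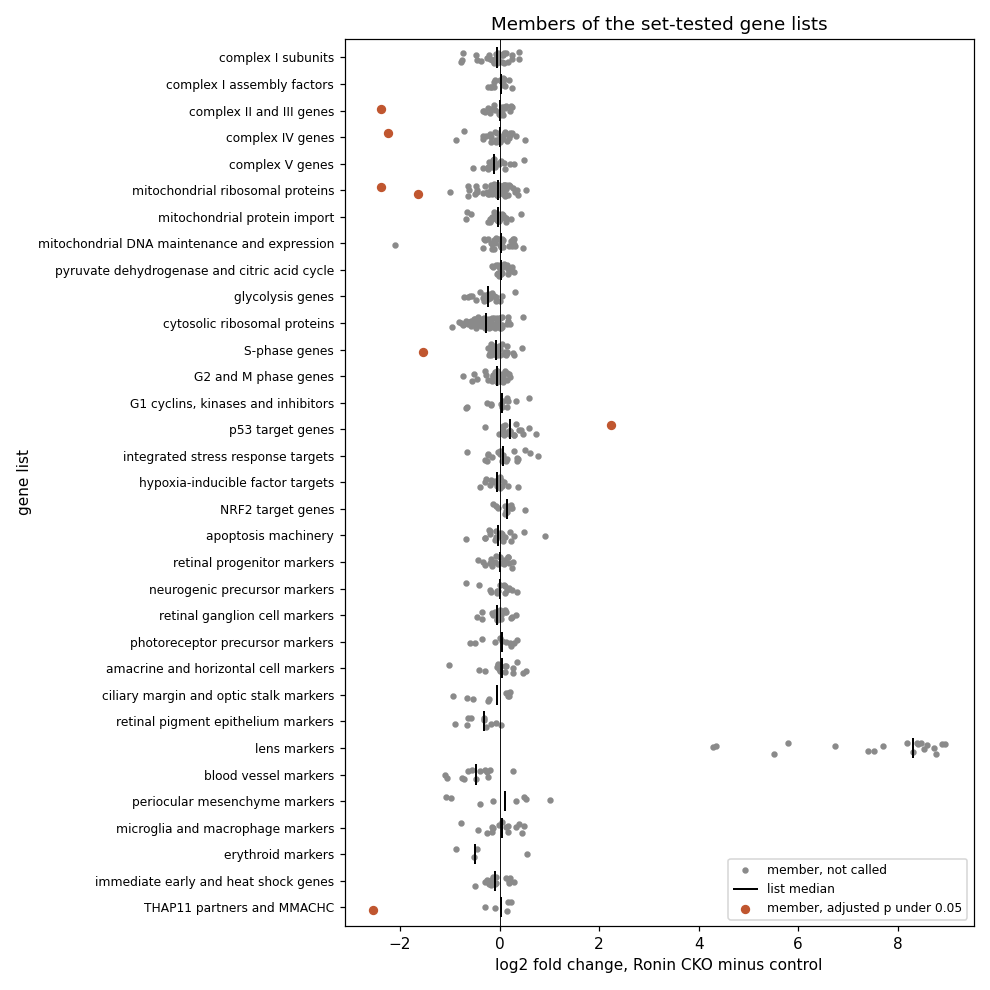
Log2 fold change (CKO minus control) of each tested member of the 33 gene lists under a set test, 1 list per line; grey points are members that did not pass, orange points passed the gene test, and black lines are list medians. Most medians lie near 0, the lens markers stand at a median of 8.30, and the called members of mitochondrial lists lie between -2.38 and -1.63.

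Tissues next to the retina were followed through marker lists. Lens markers were higher in the CKO as a set: all 19 tested members had positive log2 fold changes (median 8.30, camera adjusted p = 9.6e-17), against an adjusted p = 0.918 with an estimated correlation. The median difference on the log2 CPM scale was 5.44, and 3.59 without CKO replicate 1 (adjusted p = 2.7e-19, range 2.5e-52 to 0.918). No member passed over all genes and all 19 did adjusted over the list alone. DESeq2's Wald test called 17 of the 19 and limma-voom 0. The CKO libraries differed among themselves in this list, with summed lens CPM of 23.6, 14.5 and 16.4 in the controls and 11526, 82.8 and 843 in CKO replicates 1, 2 and 3. Cryaa, which encodes alpha-A crystallin, stood at 3.97, 1.05 and 2.86 CPM in the controls and at 3239, 34.6 and 175 CPM in the CKO (edgeR adjusted p = 0.122). It passed with DESeq2 (adjusted p = 2.9e-06), with the replicate number as a block (0.00305) and without CKO replicate 2 (0.0479). Its adjusted p lay in a range of 2.9e-06 to 0.445 over its alternatives.

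**Figure D3:**
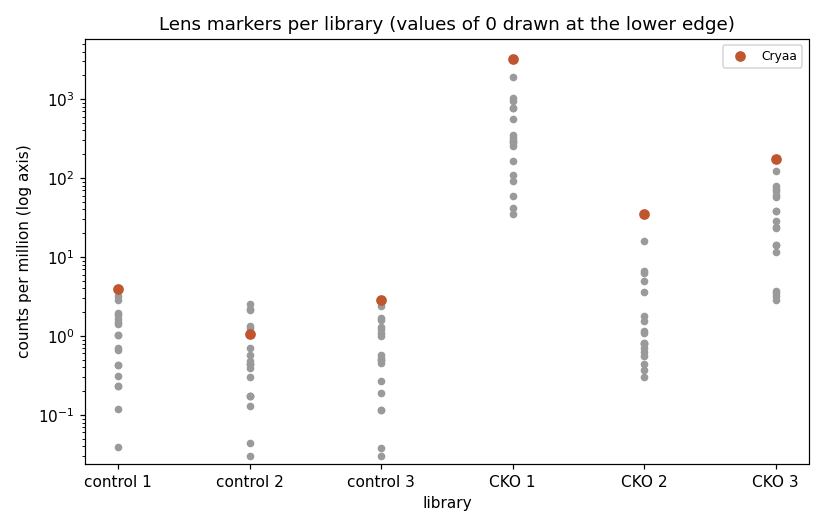
CPM on a log axis of 19 lens markers in each of the 6 libraries; each point is a gene, with Cryaa in orange, and a value of 0 is drawn at the lower edge. Cryaa reaches 3239 CPM in CKO replicate 1, 34.6 in replicate 2 and 175 in replicate 3, against at most 3.97 in a control.

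Blood vessel markers were lower as a set, with 12 of 13 members at negative log2 fold changes (median -0.48, camera adjusted p = 0.000124), against an adjusted p = 0.918 with an estimated correlation. On the log2 CPM scale of the set test the median difference was -0.44, against -0.22 without CKO replicate 2 (adjusted p = 0.0278) and -0.26 without control replicate 3 (0.00354), in a range of 8.0e-08 to 0.918 over the alternatives. None passed over all genes. Adjusted over the list alone Flt1, a receptor of vascular endothelial growth factor, was lower, at 4.10 ± 0.58 and 1.96 ± 0.23 CPM, and Kdr was at 283 ± 31.6 and 237 ± 5.78 CPM. No member passed over all genes or adjusted over the list alone among 10 retinal pigment epithelium markers (median -0.31, camera adjusted p = 0.162, Trpm1 at 29.5 ± 11.7 and 19.1 ± 0.80 CPM), 8 periocular mesenchyme markers (median 0.10, adjusted p = 0.930) or 15 microglia and macrophage markers (median 0.05, adjusted p = 0.839, Csf1r at 15.5 ± 1.01 and 15.2 ± 1.22 CPM). Col6a1, of the mesenchyme list, stood at 25.2, 110 and 44.8 CPM in the controls and at 24.3, 34.1 and 33.1 CPM in the CKO. None of 4 erythroid markers passed over all genes (median -0.49, camera adjusted p = 0.283), and Alas2, of haem synthesis, was lower adjusted over the list alone, at 5.15 ± 0.84 and 2.79 ± 0.78 CPM. The pigment epithelium set passed as lower without control replicate 2 (adjusted p = 0.0339, range 0.0339 to 0.982) and the erythroid set without CKO replicate 3 (adjusted p = 0.000113, range 0.000113 to 0.982). On the log2 CPM scale the pigment epithelium median went from -0.17 to -0.55 without control replicate 2. The erythroid median went from -0.61 to -1.14 without CKO replicate 3 and to -0.13 without CKO replicate 2.

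Of 6 genes in the list of THAP11 partners and MMACHC, Mmachc alone fell, over all genes and adjusted over the list alone (camera adjusted p = 0.811, median 0.02). Hcfc1, which encodes the partner protein HCF-1, was at 417 ± 70.1 CPM in the controls and 341 ± 3.50 CPM in the CKO (log2 fold change -0.29 ± 0.15, edgeR adjusted p = 0.875). Zfp143, a transcription factor gene, was at 41.0 ± 11.3 and 45.3 ± 2.17 CPM (log2 fold change 0.15 ± 0.21). None of the 5 genes of the list of Y-linked genes and Xist passed (median 0.23). Xist had 36 reads in control replicate 1 and between 5972 and 31382 reads in the other 5 libraries, and Ddx3y, of the Y chromosome, lay between 25.6 and 78.0 CPM in the 6 libraries. The other 5 libraries thus held reads of both genes, and control replicate 1 differed from them in Xist. The model held genotype only and took no account of this difference.

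The median, the mean or the set test's direction differed in sign for 9 lists, none of them called: complex I subunits, complex IV and complex V genes, mitochondrial DNA maintenance and expression, apoptosis, neurogenic precursor, ganglion cell and periocular mesenchyme lists, and THAP11 partners and MMACHC. In 29 lists no gene passed edgeR's test over all genes. With the lens list left out, 42 memberships of these lists lay at an unadjusted p under 0.05, and DESeq2 called 6 (Mtrf1, Bub1b, Cdkn1a in the G1 list, Chac1, Asns and Flt1) and limma-voom 0. In the 6 retinal cell class lists, 1 photoreceptor precursor marker, 2 amacrine and horizontal cell markers and 1 ciliary margin marker lay under that unadjusted p, and DESeq2 called 0. Of 35 complex I subunits, 0 lay under it and DESeq2 called 0.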

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

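The trend removal and the tests of neighbours and gene classes were chosen after the data were seen, and the other settings before. Thap11 stayed called under all 14 alternatives (log2 fold change -3.09 to -2.74), and all 131 called genes kept their direction in each of the alternatives. The CKO libraries did not overlap the controls in any of the 131, so at the same scaling leaving out a library could not turn a direction. The kept direction is therefore no test of these calls. DESeq2's Wald test called 117 genes higher, 196 lower and 205 changed at least 2-fold, and its calls include all 131. A threshold of 0.01 left 8, 31 and 39 by construction. Removing the GC and length trend called 57 genes higher, while its 152 lower and 152 changed at least 2-fold stayed within 1.5 times of the edgeR counts. Leaving out each library moved the number higher between 6 (without CKO replicate 3 or control replicate 3) and 72 (without control replicate 2), the number lower between 10 and 147, and those changed at least 2-fold between 16 and 136. Fewer libraries tend to lower the number of calls, but the size of the move depended on which library was left out. Why it did, and why the number rose without control replicate 2, was not tested. The deviations of control replicate 2 from the control mean correlated with GC content across genes (r = 0.541), with -0.390 and -0.310 in the other controls and values from -0.06 to 0.12 in the CKO. For each gene such deviations cancel out within a group, so a positive value forces a negative value among the other controls. The negative values can therefore not be read as trends of those libraries. With the replicate number as a block, 40 genes were higher, 113 lower and 149 changed at least 2-fold. Deviations of same-numbered samples correlated at 0.336, 0.107 and -0.01, and not every sample correlated best with its own number. These values do not establish a pairing by number. The value of 0.336, for the replicate 1 samples, was the highest across genotypes, so something shared by that pair is not excluded. The block also called Cryaa (log2 fold change 7.01) and the pigment epithelium list (adjusted p = 0.0445). Set tests that turned direction with a call gained or lost did so without a control: complex I subunits (adjusted p = 0.0133) and complex V genes (0.0337) without control replicate 3, mitochondrial ribosomal proteins (0.00813) and cytosolic ribosomal proteins (0.436) without control replicate 1; the cause was not tested. Over all libraries left out in turn, the adjusted p of these lists ran from 0.00474 to 0.975, 0.0337 to 0.992, 0.00228 to 0.968 and 3.8e-15 to 0.436. Of the values of single named genes and lists under the alternatives, 957 kept their side of the threshold, 58 of them with a sign change in an uncalled value, 47 lost it, 13 gained it and 4 turned. None of the 5 camera calls held with an estimated correlation or with fry (fry adjusted p from 0.314 to 0.947). With 3 libraries per group at the observed depth, and the same spread of each gene in both genotypes, 35 of 100 simulated 2-fold changes were recovered. How much of this limit comes from depth was not tested.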

Other observations

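All tests in this part were chosen after the values were seen. Zinc finger genes named Zfp or Zscan made up 21 of the 103 genes lower in the CKO and 1 of the genes higher, out of 349 tested. They were lower in 6.02% of cases against 0.575% of the other genes, and random sets of genes of similar expression held 3.46 of them on average and at most 14 (share of 10000 random sets with as many, 0.0001, the smallest they can give; odds ratio 11.1). In the 9 mitochondrial lists pooled, 4 of 287 members were lower, against a random mean of 2.66 (share of random sets 0.275). An excess of members of these 9 lists among the decreases was therefore not detected. Genes of mitochondrial proteins outside the lists were not counted, so mitochondrial genes in general were not tested. The excess of zinc finger genes lies in a class whose copies can share reads.

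Called genes lay next to one another more often than shuffled calls did: among 14454 tested genes placed in the annotation, 13 adjacent pairs were both called, each pair changed in the same direction, against a mean of 1.17 and at most 6 pairs when the calls were shuffled among genes of similar expression (share of shuffles 0.0001, the smallest they can give), which argues against chance placement. In 0 of the 13 pairs did the annotated gene bodies overlap, which argues against shared reads of overlapping models under this annotation, and with pairs of zinc finger genes left out 6 pairs remained (share 0.0007), which argues against zinc finger copies as the whole explanation. The 6 include the related alkaline phosphatase genes Akp3 and Alppl2, without which 5 pairs remained (share 0.0052); for that pair and for the 7 pairs in which both genes are zinc finger genes, reads shared between copies cannot be told apart from a change in each gene, because the counts do not show which reads match several genes. For the head-to-head part of the pattern a candidate explanation is a promoter region that serves both genes: of 1180 head-to-head pairs with starts within 1000 bases, 4 were both called, against a shuffled mean of 0.102 (share 0.0001, the smallest the shuffles can give), among them Uqcr10 with Zmat5 (log2 fold changes -2.38 and -2.45), Mmachc with Ccdc163 (-2.54 and -2.41), and Acad8 with Thyn1 (-2.05 and -2.05). This candidate does not cover the other 9 of the 13 adjacent pairs, which are not head to head. They are the 7 zinc finger pairs, Akp3 with Alppl2, and Nicn1 with Amt (log2 fold changes -0.77 and -1.64). The 5 pairs that remained above are thus the 4 head-to-head pairs and Nicn1 with Amt, so both shares rest largely on the same pairs. Outside related copies and head-to-head pairs, Nicn1 with Amt was the only adjacent called pair. Of 23 called genes with a head-to-head partner, 15 had no called partner. A linked difference in the mixed strain background stays open and untested.

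The lens transcripts may have come from lens tissue carried over into CKO replicates 1 and 3. After subtraction of the control mean, 17 of 19 lens markers kept the ratio of replicate 3 to replicate 1 within 2-fold of the median, at which replicate 1 held 12.1 times as much, and in replicate 1 the list took 1.15% of the reads, led by Cryaa at 3239 CPM. A rise of the same size in every CKO library is argued against by the summed lens CPM, which differed 139-fold between the highest and the lowest. Replicate 2 had another profile: 3 of the other 18 markers lay within 2-fold of the level predicted from Cryaa. This argues against the same lens tissue as the only source of the lens transcripts there. The prediction rests on Cryaa alone, and many markers in replicate 2 exceeded the control mean by less than 1 CPM. A smaller carry-over into replicate 2 can therefore not be excluded. Of the list, 8 markers were at 1 CPM or more in the controls, and an effect of genotype on Cryaa in replicate 2 stays open.

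The 6 libraries can be divided into 3 and 3 in 10 ways. The real split called 131 genes and the highest of the others 0, so that 1 of the 10 splits gave as many as the real one. With 10 splits the share cannot fall under 0.1, and so not under 0.05.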
